A study of Solanum lycopersicum with 4 samples.

How the data were processed

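Small RNA was sequenced from tomato (Solanum lycopersicum) leaf in 4 libraries, 2 made with HD adapters and 2 with standard Illumina adapters (IL). HD adapters carry random bases at the ends that are joined to the RNA. Per the labels' protocols, the plants grew at 25 and 18 °C by day and night with 16 hours of light, and the RNA received no TAP. TAP is tobacco acid pyrophosphatase, an enzyme that opens 5′ caps and triphosphates to a monophosphate that can be ligated. Groups and replicate numbers were taken from the sample titles. The extract protocol in the labels names standard adapters for all 4 libraries, so the 2 HD libraries rest on the titles and the adapter field alone. No label says whether the 2 libraries of a group came from separate plants or RNA preparations, so p-values measure the spread between these libraries, which may be technical.

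The deposited value is a read count for each distinct sequence, without normalization, and each sequence occurs once per library. The trimming tool, its settings and any filter the authors applied before they deposited the counts are not given in the sources used here. The deposited sequences were 17 to 34 nt long with HD adapters and 17 to 41 nt with standard adapters. The libraries held 53.9 and 26.4 M reads (M, 1e6 reads) with HD adapters (replicates 1 and 2) and 5.40 and 6.68 M with standard adapters. Each count is stored in 1 text field together with its sequence, and the planned edgeR test was not run on the counts read from it. limma 3.58.1 with voom weights took its place in R 4.3.3, and the thresholds given below replaced the planned edgeR filter. The planned genome match and RNA class shares were not run, and other departures from the plan are stated where they occur.

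Part of the reads still held adapter sequence. Reads with any 12 consecutive bases of the Illumina small RNA 5′ adapter or 3′ adapter were removed, and reads of 18 to 30 nt were kept. The match of 12 bases was chosen after the data were examined, and the adapter sequences come from general knowledge, not from the labels. This left 45.8, 23.1, 5.05 and 6.50 M reads in HD replicates 1 and 2 and IL replicates 1 and 2. At these depths 1 kept read equals 0.0218, 0.0433, 0.198 and 0.154 CPM (counts per 1e6 kept reads). The floor for a sequence with 0 reads was set at 3 reads over the group, 0.260 CPM for standard adapters and 0.0435 CPM for HD adapters. Reads are not independent molecules, so intervals and floors cover counting error only.

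Distinct sequences were tested with at least 0.676 CPM in at least 2 libraries and at least 15 reads in all, which left 136153 sequences. Libraries were scaled by the trimmed mean of M values (TMM), computed from its published formula with 30% of log ratios and 5% of levels trimmed on each side. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The log2 difference is HD minus IL on the TMM scale with its standard error (SE), whereas CPM values are per 1e6 kept reads with the standard deviation (SD) over 2 libraries. TMM raised HD over IL by 0.54 on the log2 scale relative to total counts, so a sequence can have a lower CPM with HD adapters and a log2 difference above 0. TMM was computed anew on the sequences tested with each library left out. The log2 differences of miR166, miR167 and miR482d then ranged from −4.52 to −2.51, 3.12 to 5.08 and 5.72 to 7.80. Much of the movement of a single sequence with 1 library left out is therefore a shared shift in scaling. A list of 54 miRNAs, trans-acting siRNAs and star strands in 7 groups was written from general knowledge before the data were examined, and was matched over the whole mature sequence. Suffixes mark variants within a family: .U, .G, .A, .C, .T, .CG and .GG denote differing bases, .shift a shifted start and star the passenger strand. Groups of the list were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma. Read counts summed by length and first base, 52 classes, were tested in the same way with total scaling.

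Shares of reads by length, end bases, distinct sequences at a common depth of 5.05 M reads, and the share of exact mature forms were compared as mean ± SD with exact two-sided permutation tests. With 2 against 2 libraries there are 6 splits and the smallest possible p is 0.333, so these tests cannot pass 0.05. The exact share of a miRNA is the percent of reads with its first 17 bases that are the mature sequence, given where every library had at least 100 such reads.

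Named sequences followed a rule fixed before the data were examined. It takes up to 12 listed miRNAs with the largest rises and up to 12 with the largest falls past 0.05, and the 6 listed miRNAs with the highest CPM in each group. It adds the 5 largest rises and 5 largest falls among all sequences past 0.05 with at least 100 CPM in a group, and the most abundant sequence of each library. Other listed miRNAs are named where a count of 5 or fewer needed its members, and were chosen after their values were seen. Classes followed under every setting are the called ones with at least 5% of reads in a group and those with the largest rise and fall, a rule set after class values were seen. The 4 end-base shares and 3 strand ratios followed were also chosen after the data were seen.

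The tests were tried on simulated counts with known changes. Among 106968 simulated sequences the fit called 0 unchanged ones. It recovered 0% of 2-fold, 6.52% of 4-fold, 29.2% of 8-fold and 38.0% of 16-fold changes, drawn from 38, 46, 48 and 50 changed sequences of any count. Recovery was therefore low for single sequences, and the bound it had to meet, as well as the class simulation, was revised after a first run missed a stricter one. Few changes were planted among otherwise unchanged sequences, whereas 63.3% of sequences were called in the data. Neither the recovery nor the 0 false calls therefore carries over to the comparison of HD with IL. The class test recovered 10 of 10 classes changed 2-fold with 0 false calls, and a planted stretch of 6 bases ranked 1 in a simulated scan of 136153 sequences. The changed classes were drawn only from those with few reads, and their simulated spread was set, not estimated from the data. In the data 22 of 52 classes passed, among them classes with many reads. The class recovery and its 0 false calls therefore do not carry over either.

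Alternatives were other scalings, looser and stricter filters, a replicate block, each library left out, 20 to 24 nt, thinning to 1 depth, distinct sequences in place of reads, and 3′ variants summed. Chosen after the data were examined were limma trend, limma treat, adapter reads kept, a match of 10 adapter bases, and leaving out the most abundant sequence. DESeq2 was not used. No genome sequence was used here, so matches to the genome, positions and RNA classes were not analysed here, and the origin of unlisted sequences was not determined. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, data.table (version 1.17.8) and matplotlib 3.10.9.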

Results

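Small RNA populations of tomato leaf were compared between libraries built with HD adapters and with standard Illumina adapters, 2 libraries each, from RNA without TAP treatment. The comparison asks which small RNAs each adapter set captures from the same kind of tissue. Whether the HD and IL libraries came from the same plants or RNA preparation was not established here. A difference between plants or preparations therefore cannot be told apart from one between adapters. Kept reads numbered 45.8 and 23.1 M (1e6 reads) with HD adapters and 5.05 and 6.50 M with standard adapters. Over 5150 sequences with a mean of at least 10 CPM, log2 CPM of the HD libraries correlated at r = 0.977 across sequences, and that of the IL libraries at r = 0.972. Across adapter sets r lay between 0.00419 and 0.0533 over the same sequences, which are not independent replicates and were selected on their mean. That mean was taken over all 4 libraries, so a sequence high with 1 adapter set alone could enter. Such a selection lowers r across sets and not within them, so the low r does not measure how alike the sets are. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 3.12 for the HD pair and 4.31 for the IL pair.

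Of 4 measured members of the miR482 family, which target transcripts of NLR immune receptors, miR482d and miR482a were higher with HD adapters. miR482d (TTTCCTATTCCACCCATGCCAA) stood at 478 ± 20.8 CPM (SD, n = 2) with HD adapters and 6.36 ± 1.44 CPM with standard adapters, a log2 difference of 6.75 ± 0.33 (SE). miR482a (TTTCCAATTCCACCCATTCCTA) stood at 2735 ± 393 and 70.8 ± 14.8 CPM, a log2 difference of 5.81 ± 0.32. miR482b (0.31 ± 0.27) and miR482e (0.09 ± 0.25) did not pass, and lay at −0.21 and −0.43 under total count scaling. In contrast, miR166 (TCGGACCAGGCTTCATTCCCC), a regulator of class III HD-ZIP transcription factors, was lower with HD adapters, at 336 ± 11.9 against 5738 ± 835 CPM, a log2 difference of −3.56 ± 0.20. For each of these 3 miRNAs limma gave an adjusted p of 0.000500, with both HD libraries on the same side of both IL libraries. Of 41 listed sequences with enough reads, 25 were higher and 4 lower with HD adapters past 0.05 over all sequences tested. Adjusted over the list alone, 25 were higher and 4 lower. The split over all sequences was 18 and 10 without IL replicate 1, 28 and 2 without HD replicate 2, and 18 and 2 with limma treat. Leaving out a library also moved the median log2 difference of the listed sequences, from 1.59 to 2.25 and 2.43 without HD replicates 1 and 2, and to 0.57 and 1.20 without IL replicates 1 and 2. With 3′ variants summed, miR482d lay at 4.55.

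Of the 19 measured members of the development and hormone group, 12 were higher, 2 lower and 5 did not pass. The split was 13 and 1 of 16 without HD replicate 1 and without HD replicate 2, and 10 and 4 of 19 without IL replicate 1, where miR164 (0.51) and miR171 (0.75) did not pass and miR159 (−0.97) and miR171.CG (−0.90) passed as lower. miR160, which targets auxin response factors, was higher by 5.16 ± 0.57 on the log2 scale (60.1 ± 15.8 against 2.38 ± 0.54 CPM), and by 3.53 with 3′ variants summed. The miR171.shift form, from a family that targets GRAS-domain transcription factors, was higher by 5.79 ± 0.62 (75.5 ± 20.1 against 1.87 ± 0.40 CPM). miR172, a regulator of AP2-like genes, was higher by 5.04 ± 0.91 (27.6 ± 8.22 against 1.66 ± 1.79 CPM) and by 2.89 without IL replicate 1, and miR167, which also targets auxin response factors, by 4.07 ± 0.22 (1109 ± 9.85 against 95.5 ± 13.9 CPM). miR393, which targets auxin receptor transcripts, was higher by 4.38 ± 0.55 (151 ± 62.5 against 10.1 ± 0.0436 CPM). With all 3′ variants of miR393 summed, its log2 difference was 0.86 and no longer passed (limma adjusted p = 0.0823, against 1.89e-06 to 0.00442 under the other settings). miR156.U, of the family that targets SPL transcription factors, was lower by −1.14 ± 0.17 (855 ± 137 against 2696 ± 392 CPM). It lay at −0.21 without HD replicate 1, −0.28 without HD replicate 2 and −2.08 without IL replicate 1. In CPM both HD libraries (758 and 951) lay below both IL libraries (2418 and 2973), so most of this movement lies in the scaling of those fits.

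The highest listed sequence with HD adapters was miR162, which targets DCL1, at 7503 ± 305 against 2130 ± 79.2 CPM, a log2 difference of 2.34 ± 0.15 (limma adjusted p = 0.000515), or 1.502 without IL replicate 1. With standard adapters miR166 ranked first, followed by miR396 (TTCCACAGCTTTCTTGAACTG), a regulator of GRF transcription factors. miR396 stood at 3824 ± 827 CPM with HD and 4670 ± 612 CPM with standard adapters, and did not pass (log2 0.25 ± 0.28). Its variant miR396.T, which ends in another base, was higher by 2.95 ± 0.36 (1704 ± 486 against 317 ± 18.4 CPM). miR159 and miR166star also did not pass, with log2 differences of 0.06 ± 0.22 and 0.03 ± 0.25. Under total count scaling miR396, miR159 and miR166star lay at −0.29, −0.46 and −0.49. Among the fits that kept every library, 1 of them passed as higher with 3′ variants summed and 1 with the stricter filter. Without HD replicate 1 miR396, miR159 and miR166star lay at 0.76, 1.09 and 1.22, and without HD replicate 2 at 1.47, 0.83 and 0.66. In CPM, however, miR396 and miR166star in HD replicate 2 (3239 and 3064) lay below both IL libraries (5102 and 4237, 3176 and 3244). In HD replicate 1, miR159 and miR166star (1516 and 1739) also lay below both (2094 and 2948 for miR159). These positive values therefore rest largely on the scaling. Without IL replicate 1 miR159 lay at −0.97.

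In the group that targets immune receptors, 4 of 8 members were higher (miR482a, miR482d, miR5300 and miR6022), 2 lower and 2 did not pass. The split was 6 and 2 without HD replicate 1, 6 and 1 without HD replicate 2, and 3 and 3 without IL replicate 1. miR6024 was lower by −1.45 ± 0.28 (25.2 ± 4.14 against 99.5 ± 0.50 CPM) and miR6027 by −1.74 ± 0.23 (25.8 ± 4.10 against 123 ± 15.7 CPM). Without HD replicate 1, HD replicate 2 and IL replicate 1, miR6024 lay at −0.87, −0.28 and −2.27, and miR6027 at −0.81, −0.87 and −2.66. In CPM both miR6024 and miR6027 were lower in each HD library than in each IL library. With 3′ variants summed miR6027 lay at −0.79. Of the 4 measured members of the silencing machinery group, miR162, miR390 and miR403.C were higher, and miR168, which targets AGO1, stood at 478 ± 58.5 and 823 ± 3.2 CPM without passing, but passed as lower without IL replicate 1 (−1.06) and IL replicate 2 (−0.94). In the nutrient and copper group 3 of 12 members had enough reads. Of these, miR398 and miR398.A, which target copper superoxide dismutases, were higher by 3.05 ± 0.31 and 3.53 ± 0.29 (miR398.A by 2.26 with 3′ variants summed), and miR397.shift did not pass in the main setting. The median over the group was 3.05, and 0.91 and 1.34 without IL replicates 1 and 2, where 4 members were measured. The 3 measured members of the remaining tomato group were all higher, among them miR828, with 88 HD reads and 0 IL reads, at least 4.92-fold higher over the group floor. miR167.GG, with 60 and 0 reads, was at least 3.35-fold higher, and miR169.G, with 97 and 1 reads, had a CPM ratio of 16.3 (exact 95% counting interval 2.85 to 649). Of 3 star strands, miR396star was higher, and the 1 measured trans-acting siRNA, TAS3.D7, did not pass in the main setting. The median log2 difference of the star strands was 0.31, and 1.22 and 1.40 without HD replicates 1 and 2. Under total count scaling miR403.C, miR4376 and miR396star did not pass (limma adjusted p = 0.189, 0.0613 and 0.0501), miR168 did (−0.79), and miR6024 and miR156.U did not pass limma treat against a 2-fold change (0.149 and 0.338). Without IL replicate 1, miR6022 (0.56), miR403.C (0.13), miR4376 (0.36), miR1919 (0.58) and miR396star (0.77) did not pass, nor did miR403.C (0.35) and miR1919 (0.65) without IL replicate 2. Of the listed sequences, 13 had too few reads for the test.

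As groups, 0 of 7 sets passed camera at the preset correlation after adjustment. All 41 listed sequences together had an unadjusted p of 0.0263, an adjusted p of 0.184, and an adjusted p of 0.820 with an estimated correlation. Only that set had an unadjusted camera p below 0.05, and fry, which asks whether members move one way on balance without comparing them with other sequences, gave p from 0.00287 to 0.0807. The median log2 difference was 1.59 over the listed sequences, unchanged with miR828 and miR167.GG at their bounds, and 1.01 over all sequences tested. The latter depended on depth and filter. After thinning the medians were 1.42 over the listed and 0.17 over all sequences tested, and with the stricter filter 1.96 and 0.03. Without HD replicate 1 or without HD replicate 2, 6 of 6 sets passed camera at the preset correlation, and 0 with an estimated correlation (adjusted p from 0.423 to 0.490). With the stricter filter 2 of 6 passed, the development and hormone group (adjusted p = 0.0414) and all listed sequences (0.00683), each at 0.631 with an estimated correlation.

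**Figure D1:**
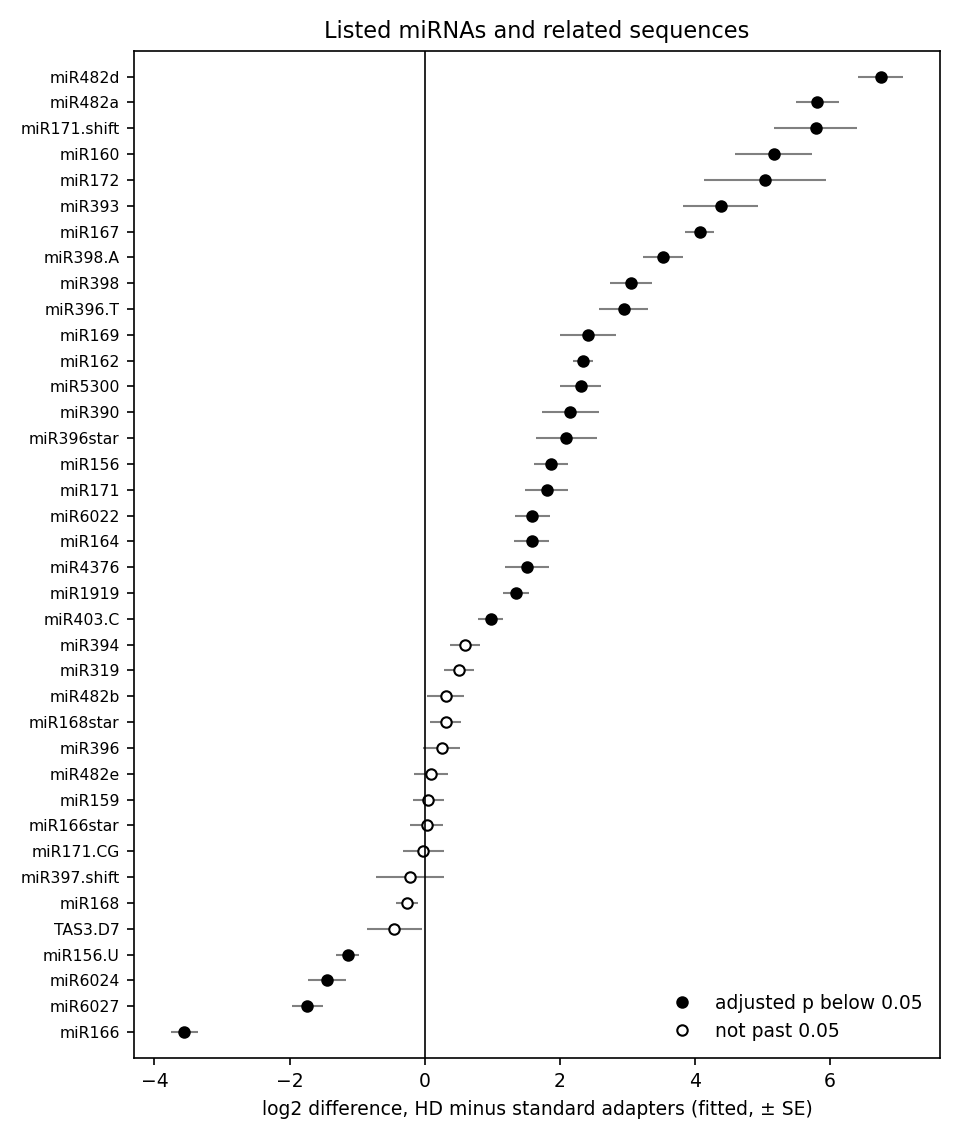
Fitted log2 difference (HD minus standard adapters, x axis) of each listed sequence with more than 3 reads in both groups (y axis), with bars of 1 SE and 2 libraries per group. Values run from −3.56 for miR166 to 6.75 for miR482d, filled points passed 0.05 and open points did not; under total count scaling miR319, miR482b, miR168star, miR396, miR482e, miR159 and miR166star lie below 0.

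Among all sequences, several were seen with 1 adapter set and not with the other. The 27-nt CTGACTGGCCAGCTCACGGCTGTCCAG stood at 3291 ± 550 CPM with HD adapters and had 0 IL reads, at least 12183-fold higher. Its shorter forms CTGACTGGCCAGCTCACGGCTGTCCA and TGACTGGCCAGCTCACGGCTGTCCAG were at least 1372-fold and 499-fold higher. The 24-nt AGCCAATGATGATTTTTATATAAA stood at 1861 ± 27.6 CPM with HD adapters and 0 with standard adapters, at least 7194-fold higher. The 28-nt AGCCAATGATGATTTTTATATAAATATT, which begins with the same 24 bases, stood at 873 ± 41.8 CPM with standard adapters and had 1 HD read, an IL to HD ratio of 59935 (exact 95% counting interval 10755 to 2367530). GTAATCCATCCCATGTACATCAAT, at 617 ± 131 CPM with HD adapters, had 3 IL reads, a ratio of 2494 (interval 853 to 12094).

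The sequences AGGATGCTGACATTGTTA (149 ± 9.45 CPM with standard adapters) and ATGATCGGGATAGCGAACCAAAAGCTA (145 ± 29.1 CPM) had 0 HD reads and were at least 3446-fold and 3400-fold lower with HD adapters. TCAACGAGAACAGAAATCTCGTG stood at 127.98 ± 68.5 CPM with standard adapters and had 2 HD reads, an IL to HD ratio of 4620 (interval 1277 to 38181). GCTCAACGAGAACAGAAATCTCGTG stood at 113 ± 67.3 CPM and 0.0653 ± 0.0311 CPM, a log2 difference of −9.97 ± 0.58 that rests on 5 HD reads and lay at −9.35 without HD replicate 1 and −8.50 without HD replicate 2. The most abundant sequence of all 4 libraries, the 22-nt AGTTACTAATTCATGATCTGGC, took 2.48 ± 0.60% of reads with HD and 8.40 ± 0.46% with standard adapters, a log2 difference of −1.25 ± 0.14 (limma adjusted p = 0.00133). It lay at −2.001 without IL replicate 1, −1.99 without IL replicate 2, −0.24 without HD replicate 1 and −0.49 without HD replicate 2. In CPM both HD libraries (20533 and 29065) lay below both IL libraries (87195 and 80759). Among the fits that kept every library, this most abundant sequence did not pass with limma trend or treat, where its adjusted p reached 0.194 and 0.120. Its call is not claimed to hold with 1 library left out, where only the log2 difference is given.

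Of 136153 sequences tested, limma called 86174, of which 58550 were higher and 27624 lower with HD adapters. The split depended on scaling, depth and filter. Total count scaling gave 46914 higher and 35797 lower, thinning to the smallest library 16924 and 13076 of 46196 tested, and the stricter filter 3169 and 2948 of 7426. The looser filter called 231689 of 733851. Leaving out 1 library changed how many sequences met the filter, to 39137 (HD replicate 1), 38702 (HD replicate 2), 174222 (IL replicate 1) and 170493 (IL replicate 2). The median log2 difference was then −0.09, −0.10, 1.01 and 1.19.

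The 3′ ends of miRNAs differed between adapter sets. The exact mature form made up 65.7 ± 7.99% of miR393 reads with HD and 5.67 ± 0.30% with standard adapters. It made up 81.2 ± 0.80% and 17.9 ± 6.58% of miR482d reads, and 89.5 ± 0.41% and 37.0 ± 8.86% of miR398.A reads. The order was opposite for miR6027, with 40.0 ± 1.05% against 77.1 ± 0.64%, and miR166, with 50.2 ± 2.29% against 83.0 ± 3.43%. For miR396 the shares were 55.6 ± 0.57% and 85.7 ± 0.49%, but the listed miR396.T, which has the same first 17 bases, took 24.6% and 5.85% of the same reads. Of 29 listed sequences with at least 100 reads in every library, 14 had a higher exact share in both HD libraries than in both IL libraries and 13 a lower one, where chance separates 33.3%. These counts hold miR396 with miR396.T and miR167 with miR167.GG as separate members, although each pair shares its reads. Among the 14 is miR167.GG, at 0.0649% in HD libraries and 0 of 786 and 1190 reads in IL libraries, too few reads for such a share to show. The exact permutation p of each separated sequence was 0.333, the smallest that 2 against 2 libraries allow.

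**Figure D2:**
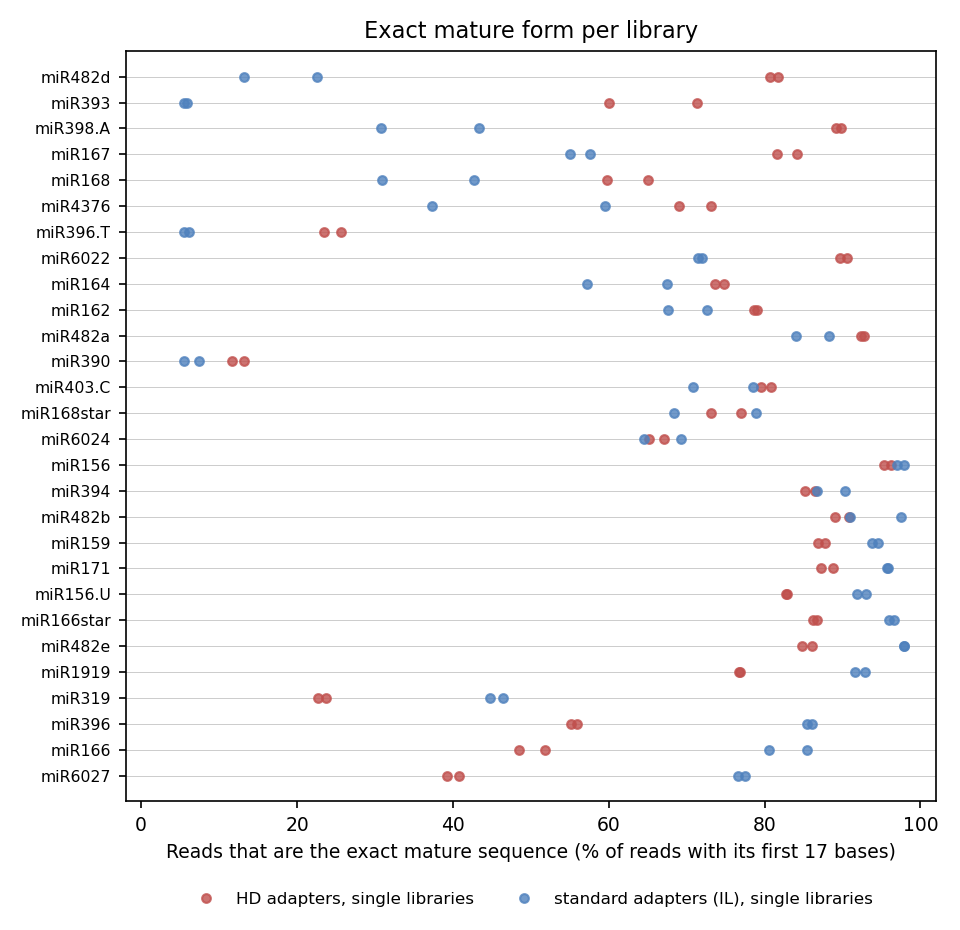
Percent of reads with the first 17 bases of a listed sequence that are its exact mature form (x axis) for listed sequences with at least 100 such reads in every library (y axis; miR167.GG, below 0.1% in every library, is not drawn). Each point is 1 library; miR482d lies at 81.2% with HD and 17.9% with standard adapters on average, miR6027 at 40.0% and 77.1%.

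The 24-nt class, the size of heterochromatic siRNAs, made up 45.3 ± 1.56% of reads with HD and 33.7 ± 2.77% with standard adapters. The 23-nt class made up 15.8 ± 0.82% and 13.1 ± 0.36%, the 21-nt class, the size of most miRNAs, 11.3 ± 0.51% and 11.9 ± 0.22%, and the 22-nt class 11.5 ± 0.74% and 17.1 ± 0.0146%. For each of these 4 lengths the libraries of the groups did not overlap (exact permutation p = 0.333). Without AGTTACTAATTCATGATCTGGC the 22-nt class made up 9.25 ± 0.19% and 9.45 ± 0.43%, and the groups overlapped. Over distinct sequences the 22-nt difference turned to 1.38 percentage points higher with HD adapters and that of 24 nt was 3.002.

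**Figure D3:**
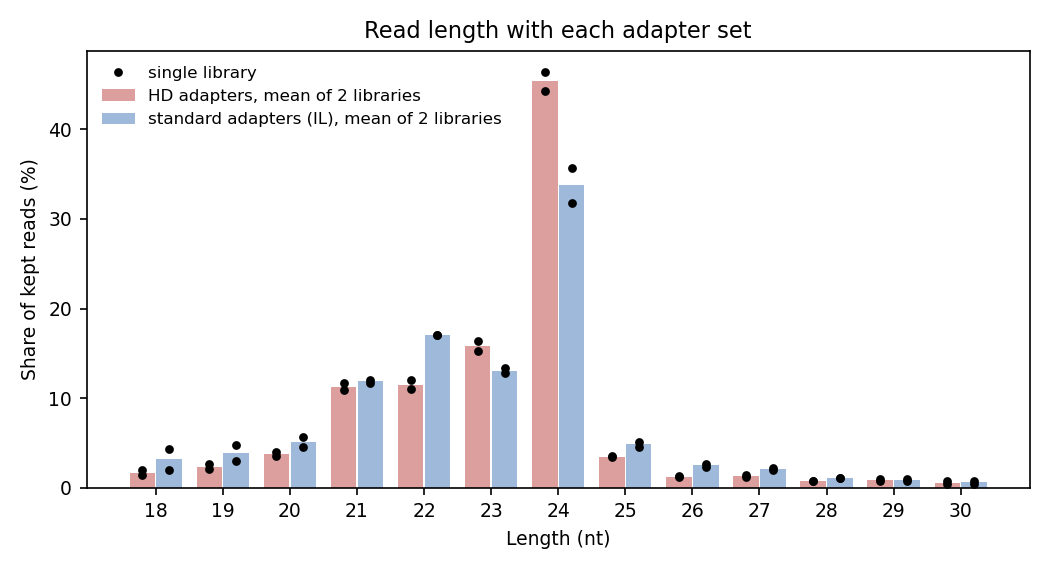
Share of kept reads in percent (y axis) by length in nt (x axis). Bars are means of 2 libraries and points are single libraries; the 24-nt class stands at 45.3% with HD and 33.7% with standard adapters.

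By length and first base, 22 of 52 classes passed with total scaling, 5 higher and 17 lower with HD adapters. Under TMM scaling 8 were higher and 10 lower, and with adapter reads kept 9 and 17. The higher ones were 24-nt sequences starting with G (log2 0.77 ± 0.11, 7.13 ± 0.34% against 4.13 ± 0.39%) or A (0.49 ± 0.10), 23-nt ones starting with A (0.71 ± 0.09) or G (0.47 ± 0.12), and 22-nt ones starting with G (0.62 ± 0.13). Over distinct sequences the 24-nt class starting with G lay at 0.43 and the 23-nt class starting with A at 0.47. The class of 22-nt sequences starting with A, at 5.19 ± 0.61% against 11.0 ± 0.31%, was lower by −1.08 ± 0.10 (limma adjusted p = 0.000726), but lay at −0.07 without AGTTACTAATTCATGATCTGGC (adjusted p = 0.608) and at 0.50 over distinct sequences, within a range of adjusted p from 1.9e-10 to 0.608. The 21-nt class starting with T, at 4.58 ± 0.0782% against 5.74 ± 0.39%, was lower by −0.33 ± 0.09 (adjusted p = 0.0278). It did not pass under TMM scaling (−0.01, adjusted p = 0.949, within a range of 0.00716 to 0.949) or with adapter reads kept (−0.16). It also did not pass with the replicate block (−0.33) or without HD replicate 1 (−0.31), HD replicate 2 (−0.35) or IL replicate 2 (−0.26), where its value stayed closer to the main one. The 27-nt class starting with T was lower by −1.74 ± 0.16 (0.204 ± 0.0225% against 0.692 ± 0.0503%). Leaving out HD replicate 1 left 2 classes higher and 6 lower, IL replicate 1 left 3 and 11, and IL replicate 2 left 3 and 13. Sequences of 24 nt starting with A did not pass with the replicate block (0.49), over distinct sequences (0.13) or without HD replicate 1 (0.46), and lay at 0.80 under TMM scaling. Those of 23 nt starting with G did not pass with the replicate block (0.47) or without HD replicate 1 (0.42), IL replicate 1 (0.44) or IL replicate 2 (0.53), nor those of 22 nt starting with G when any 1 library was left out (0.60 to 0.64).

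Among end bases, 4 shares chosen after the data were seen are given here. At the last base, C made up 27.4 ± 1.11% of reads with HD and 40.8 ± 0.30% with standard adapters, and G 20.3 ± 1.0% and 11.8 ± 0.22%. At the base before it, G made up 29.4 ± 1.86% and 37.6 ± 0.68%, and at the first base G made up 18.3 ± 0.17% and 13.4 ± 0.0122%. The groups did not overlap for these 4 shares (exact permutation p = 0.333). AGTTACTAATTCATGATCTGGC itself ends in GC, and without it the last-base difference in C was −9.75 percentage points in place of −13.3, and that of G before the last base −4.22 in place of −8.15. Among 21-nt reads G before the last base differed by −0.061 percentage points.

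At a common depth of 5.05 M reads, HD libraries held 2.37 ± 0.181 M distinct sequences and IL libraries 1.64 ± 0.0303 M, a ratio of 1.45 (exact permutation p = 0.333). The 10 most abundant sequences took 5.96 ± 0.98% and 14.0 ± 0.11% of reads, and the 100 most abundant 12.5 ± 1.66% and 23.2 ± 0.35%. Of the distinct sequences at that depth, 82.1 ± 1.29% and 78.1 ± 0.17% were seen once.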

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

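The test of the most frequent bases after the adapter was chosen after the result was seen, whereas the test of their effective number was written before its outcome was known. Reads outside 18 to 30 nt or with adapter sequence were left out of the main comparisons and enter only the settings that name them, and each stood above what 0 reads allow, except those of 35 to 41 nt in HD libraries. Reads of 17 nt made up 1.36 ± 0.42% of reads without adapter in HD libraries and 2.65 ± 1.92% in IL libraries. Reads of 31 to 34 nt made up 1.90 ± 1.42% and 1.57 ± 0.87%, and the most abundant of them was the 32-nt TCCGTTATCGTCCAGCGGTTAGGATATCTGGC, with 198296 and 29288 reads in HD replicates 1 and 2 and 14878 and 8174 in IL replicates 1 and 2. Reads of 35 to 41 nt made up 0.0677 ± 0.0172% in IL libraries and were not seen in HD libraries. Reads with 12 bases of the 3′ adapter made up 0.0138% in HD libraries and 0.000177% in IL libraries.

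Reads with 12 bases of the 5′ adapter made up 10.9 ± 0.72% of HD libraries and 0.229 ± 0.18% of IL libraries. Of those that also held the last 8 bases of the adapter, 82.9% in HD libraries had exactly 4 bases after its end, and 75.2% in IL libraries had 0. In the 7.14 M (1e6) HD reads with the last 12 adapter bases and exactly 4 more, the 4 bases took every possible form, with an effective number of 132, just over the bound set beforehand, and at most 3.45% for any form. Leaf RNA from a few places that resemble the adapter would bring a few forms, and the 3.45% argues against it for these reads, whereas RNA from many such places was not tested. A candidate explanation is a ligation product of the HD 5′ adapter with its own random bases and no leaf RNA. The forms were not used equally, no biological explanation other than leaf RNA from a few places was tested, and keeping these reads changed the ratio of distinct sequences from 1.45 to 1.34.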

How the results depend on the processing

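Limma trend, limma treat, adapter reads kept, the match of 10 adapter bases, leaving out the most abundant sequence, and list tests under other scalings or thinning were chosen after the data were seen. Not run were DESeq2's Wald test and edgeR's treat test (limma trend and treat stand in their place), genome match shares, RNA class shares and length shares of genome-matched reads. The nutrient and copper set had under 2 members with the stricter filter or without an HD library. Classes, end-base shares and strand ratios followed here were picked after their values were seen. For named sequences, left-out libraries aside, 380 settings kept direction and side of the threshold, 11 reversed, 5 were weaker and 2 stronger. The count of called sequences was 231689 with the looser filter, 6117 with the stricter one and 30000 after thinning, where 733851, 7426 and 46196 sequences were tested, and 21507 to 135211 with 1 library left out. Counts of classes were 8 to 20, and of passing sets 0 to 6, with 1 library left out, and 2 sets passed with the stricter filter. With 1 library left out, the lone sample is assumed to vary like the other group. The listed miRNAs called stayed between 20 and 31. The log2 difference of miR166star turned to −0.49 (total count scaling), −0.15 (20 to 24 nt), −0.13 (thinned), −0.0928 (adapter reads kept) and −0.0776 (without the most abundant sequence), that of miR159 to −0.46, −0.12, −0.0962, −0.0676 and −0.0609 in that order, and that of miR396 to −0.29 with total counts. With 1 library left out they ranged from −0.76 to 1.22, −0.97 to 1.09 and −0.59 to 1.47. None of these 3 passed in the main setting. The scaling differed between these settings, and any further cause was not tested. In percentage points, HD minus IL, the 22-nt difference of −5.56 became 1.38 over distinct sequences, −7.99 within 20 to 24 nt and −0.20 without the most abundant sequence. The 21-nt difference of −0.58 became −1.80 within 20 to 24 nt and −1.37 without that sequence, and ranged from −0.94 to −0.22 with 1 library left out. The 23-nt one of 2.76 became 1.88 within 20 to 24 nt and 1.96 without that sequence. The 24-nt one of 11.6 became 3.002 over distinct sequences and 7.80 with adapter reads kept. The class of 22-nt sequences starting with A turned to 0.50 over distinct sequences. For last-base C, last-base G, G before the last base and first-base G, the differences of −13.3, 8.46, −8.15 and 4.83 became −5.23, 5.36, −5.13 and 3.35 over distinct sequences. They became −19.2, 12.7, −0.061 and 3.57 at 21 nt, −5.52, 4.41, −9.86 and 3.49 at 24 nt, and −14.6, 10.6, −6.73 and 5.80 with adapter reads kept. Without the most abundant sequence those in C, G before the last base and first-base G were −9.75, −4.22 and 4.07. The share in the 100 most abundant sequences differed by −12.02 with adapter reads kept, against −10.8. Apart from the removed sequence and the shorter list of lengths, the cause was not tested. The replicate block called 82282 sequences, 29 listed miRNAs and 25 classes, and the deviations of same-numbered libraries correlated at −0.0404 over 5150 sequences. Sequences could enter through 1 adapter set alone, where the other set adds mostly counting noise. This value therefore cannot decide whether same-numbered libraries are pairs, and the main tests did not take them as pairs. IL depth limits sequences below 0.260 CPM.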

Other observations

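Tests of thinning, of end bases, of match length, and of holders in a linear model or without GAATTC were written before their outcomes were known, and the patterns they address, the scan of 6-base stretches, the strand ratios and the values per position were chosen after the data were seen. The 2 strands of miR166 changed order between adapter sets. The ratio of miR166 to miR166star reads was 0.198 and 0.107 in HD replicates 1 and 2, and 1.62 and 1.95 in IL replicates 1 and 2. The difference in log2 ratio was −3.61 (exact permutation p = 0.333, the smallest possible with 2 against 2 libraries), between −4.06 and −3.17 with 1 library left out and −3.04 with 3′ variants summed, and it does not depend on scaling. The ratio of miR168 to miR168star differed by −0.56 (−0.77 to −0.35 with 1 library left out), from 2.48 and 3.31 to 4.29 and 4.16. That of miR396 to miR396star differed by −1.92 (−2.64 to −1.21), with 58 star reads in IL replicate 1. In each of these 3 pairs the exact guide form was thus lower relative to its exact star with HD adapters. With 3′ variants summed the groups overlapped for miR396 (366293 to 2295 reads in HD replicate 1, 31997 to 202 in IL replicate 2).

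Overlap between libraries was low with either adapter set. At the common depth of 5.05 M (1e6) reads, the HD libraries shared 24.2% of the distinct sequences of the smaller library and the IL libraries 23.98%, whereas pairs across adapter sets shared 19.0 to 19.2%. Shared sequences took 57.7 and 62.9% of reads within the HD pair and 72.2 and 71.0% within the IL pair. In pairs across adapter sets they took 44.0 to 49.9% of HD reads and 65.5 to 66.8% of IL reads.

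Sequences with the stretch ATTCCA, the complement of the first 6 bases of the standard 3′ adapter (TGGAAT), had the highest mean log2 difference of 4014 stretches scanned, at 3.64 ± 2.48 (SD) over 2640 sequences against 0.87 over the others, whereas the stretch in the adapter's own sense ranked 1995 with a mean of 0.84. Linear terms for end bases, GC content and length left holders 2.28 ± 0.05 (SE) above other sequences, and holders without GAATTC lay 2.66 above them, which argues against base composition and against trimming at an adapter-like stretch as the whole cause. Sequences whose longest match to the complement of the adapter start was 7 or more bases lay 2.21 above those with 4, but all of them hold ATTCCA, so this difference restates the scan. Means rose from 0.48 to 0.89, 1.02 and 1.78 with 1 to 4 bases, stepped by −0.16 ± 0.09 (SE) to 1.63 with 5, and among holders were 3.26 ± 0.08 with 6 and 3.99 ± 0.06 with 7 or more, a step that was not set as a test beforehand. Whether the RNA pairs with the start of the standard 3′ adapter stays open, and no biological explanation was tested.

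The listed miRNAs with ATTCCA were miR482d, miR482a, miR828 and miR5300, all higher with HD adapters. They were among the sequences scanned, so their direction is not separate support for the stretch. Of all 2640 holders 84.7% were called higher, and of the 41 listed sequences tested 25 were. By place in the sequence, holders had a mean log2 difference of 5.17 ± 1.49 (SD, 365 sequences) with the stretch at the 3′ end, 4.86 ± 1.43 with 1 to 3 bases after it, and 2.28 ± 3.05 with 13 to 24 bases after it. Overlapping sequences are not independent: averaged over 776 different surroundings of the stretch, the mean was 3.19 ± 0.09 (SE).

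The log2 difference varied widely from sequence to sequence, with an SD of 2.78 over 136153 sequences. With all libraries thinned to 1 depth the SD over the same sequences was 0.942 times that at full depth. Thinning leaves the counting noise of the shallow IL libraries in both SDs, and the sequences were chosen at full depth. The ratio therefore cannot exclude shallow IL counts as a source. Over 8505 sequences with at least 10 CPM in a group the SD was 3.42 at full depth and 3.35 after thinning. The first 4 and last 4 bases predicted the difference of sequences left out of the model with a squared correlation of 0.126, against 0.0311 for 8 inner bases and 0.0561 for GC content and length. Ligation preferences for the end bases are consistent with that share, and most of the variation stays open. No biological explanation was tested.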
